A study of Homo sapiens with 60 samples.

How the data were processed

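RNA of SW1783 cells, an established human astrocytoma line, was sequenced after 24 h with a vehicle or with the water extract of a herb or herbal formula at 500, 100 or 20 µg/mL, called the high, medium and low dose. Per the labels' protocols, libraries were made from total RNA with a directional MGI kit for mRNA and sequenced as paired ends on an MGI instrument. Per the submitters' processing notes, the authors used FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with the builds hg38 and GRCh38. The annotation release, the strand setting of the counting and any read filters are not given in the sources used here. Because the strand setting is unknown, reads of a gene and its antisense partner may not have been told apart. RSEM divides reads that fit several places by estimate, so values of close paralogs and of overlapping genes are uncertain.

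The deposited values were expected counts per gene, the estimated counts that RSEM gives, for 60675 genes in 60 libraries, and 9.22% of the values were not whole. All columns were matched to a sample by name, and each line was 1 gene. Of the gene identifiers, 42020 had a symbol and 57055 were in the reference annotation used here for coordinates on GRCh38. Total counts per library ranged from 18.9 to 36.4 M (mega). The expected counts were rounded to whole numbers before the tests. Replicate libraries of a group were compared pair by pair with a chi-square statistic over genes with a count of at least 20. It ranged from 1.74 to 21.9 per degree of freedom, so every pair differed by more than sampling noise and each library was counted as a replicate. The labels name replicates but do not say that they came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

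Groups were taken from the sample labels: 1 vehicle group and 18 groups of an extract at a dose, with 3 libraries each. The labels name 6 extracts with 3 libraries per dose and a 7th, Bojungikgi-tang, with 1 library per dose. The 57 libraries of the 19 groups were fitted together, so that all groups shared an estimate of the spread. The groups compared, the gene lists, the rule for the genes named and the tests were chosen before the data were examined. The design text of the series also names other extracts and 3 compounds as positive controls, as well as a rule that lowers the doses of toxic extracts, and these are not analysed here. The labels give 0.1% DMSO for the vehicle (design text 2%) and no value for extracts.

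Genes were kept with edgeR's filterByExpr by group, which left 17190, and libraries were scaled by TMM factors. Each comparison was tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2 scale with the standard error (SE) of the fit, and levels are CPM, the counts scaled by library size as edgeR does, with TMM factors, as mean ± SD of 3 libraries. Each dose was compared with the vehicle, and the high dose with the low dose of the same extract. At the high dose, the extracts whose sample codes fall in the same set were compared with each other, as were their differences between high and low dose.

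The sample codes fall into sets. The vehicle is in set B1, Citri Unshius Pericarpium and Cimicifugae Rhizoma in set 5, Bupleuri Radix and Aconiti Lateralis Radix Preparata in set 6, Yijung-tang and Banhasasim-tang in set 7, and Bojungikgi-tang in set 8. What the sets stand for is not given in the sources used here. Code set, DMSO and treatment cannot be told apart against the vehicle, while an extract's doses share a set. All comparisons with the vehicle also share its 3 libraries, so no overlaps or correlations between extracts were computed from them. Within an extract, the high dose against the vehicle and against the low dose share the high-dose libraries, which favours an overlap of their calls.

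For each extract the genes named are among the 10 largest rises and the 10 largest falls at the high dose. A gene qualified if it had a symbol, was called with the same sign against the vehicle and against the low dose, and had at least 5 CPM in the higher group. In addition, its 3 high-dose libraries had to lie beyond the 3 vehicle libraries. Members of the gene lists are named besides. In all, 33 gene lists of pathways, stress responses, cell type markers and RNA quality were tested with camera (limma 3.58.1) on voom log2 CPM. The correlation between genes was preset at 0.01, for the high dose against the vehicle and against the low dose, with Benjamini-Hochberg adjustment over 396 tests. Camera with an estimated correlation and fry were run beside it, and both depend slightly on the order of the groups in the model, which was alphabetical. Camera called 177 tests, of which 125 held with the estimated correlation and 174 with fry, and none changed direction. In no called test did the median, the mean and the test of a list differ in sign. SLC7A11 is in both the NRF2 and the ATF4 list, NQO1 in the AhR and the NRF2 list, and DUSP1 in the glucocorticoid and the immediate early list. Bojungikgi-tang was described by ratios of CPM without a test, with list medians set among 10000 random lists matched on mean expression. Its genes are the 10 largest rises and falls with at least 10 CPM and values ordered over the doses.

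The test was tried on simulated counts of Citri Unshius Pericarpium at the high dose against the vehicle (16960 genes). Of 50 genes each changed 1.25-, 1.5-, 2- and 4-fold it recovered 54%, 76%, 88% and 98%, with 9 calls among 16760 unchanged genes. Simulated Cimicifugae Rhizoma counts with no changed gene gave 0 calls with edgeR, and 4.79% of 16960 genes had an unadjusted p under 0.05. This does not gauge false calls in real groups of unequal spread. The alternatives were DESeq2 1.42.0, its size factors, no filter on low counts, the replicate number as a block, a fit of the compared groups alone and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.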

Results

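Gene expression was measured by RNA sequencing in SW1783 astrocytoma cells after 24 h with water extracts used in Korean herbal medicine. Citri Unshius Pericarpium is a dried mandarin peel, Cimicifugae Rhizoma a rhizome, Bupleuri Radix a root and Aconiti Lateralis Radix Preparata a processed aconite root. Yijung-tang, Banhasasim-tang and Bojungikgi-tang are decoctions of several herbs. Each of the first 6 had 3 libraries at 500, 100 and 20 µg/mL, Bojungikgi-tang had 1 library per dose, and the vehicle (0.1% DMSO) had 3. Mean totals were 20.77 M (mega) counts in the vehicle, 22.92 M in code set 5, 21.83 M in set 6, 27.06 M in set 7 and 29.7 M in set 8. Mitochondrially encoded genes took 5.14% ± 0.134 (SD, n = 3) of the counts in the vehicle. Their share was 5.76% ± 0.704 in set 5, 7.19% ± 2.12 in set 6 and 6.4% ± 0.544 in set 7 (SD, n = 18 each). In set 5, the third low-dose library of Citri Unshius Pericarpium and the third high-dose library of Cimicifugae Rhizoma stood apart from their groups. Their root mean square deviations were 0.199 and 0.219 on the log2 scale, against at most 0.142 in any other library, and their mitochondrial shares were 7.37% and 7.7%. The first 2 principal components of the 57 libraries took 22% and 6.41% of the variance.

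The number of genes called by edgeR's quasi-likelihood test rose with the dose of Aconiti Lateralis Radix Preparata, from 377 at 20 µg/mL to 10386 of 17190 at 500 µg/mL. At the high dose against the vehicle, 5592 genes were called for Cimicifugae Rhizoma (2589 up and 3003 down), 5506 for Yijung-tang (2630 and 2876) and 3720 for Citri Unshius Pericarpium (1688 and 2032). There were 2889 for Banhasasim-tang (1373 and 1516) and 1206 for Bupleuri Radix (517 and 689). Most changes were small. A change of at least 2-fold was reached by 874 genes up and 1062 down with Aconiti Lateralis Radix Preparata. With Citri Unshius Pericarpium, 99 genes reached it up and 45 down, and with Bupleuri Radix 20 and 28.

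**Figure D1:**
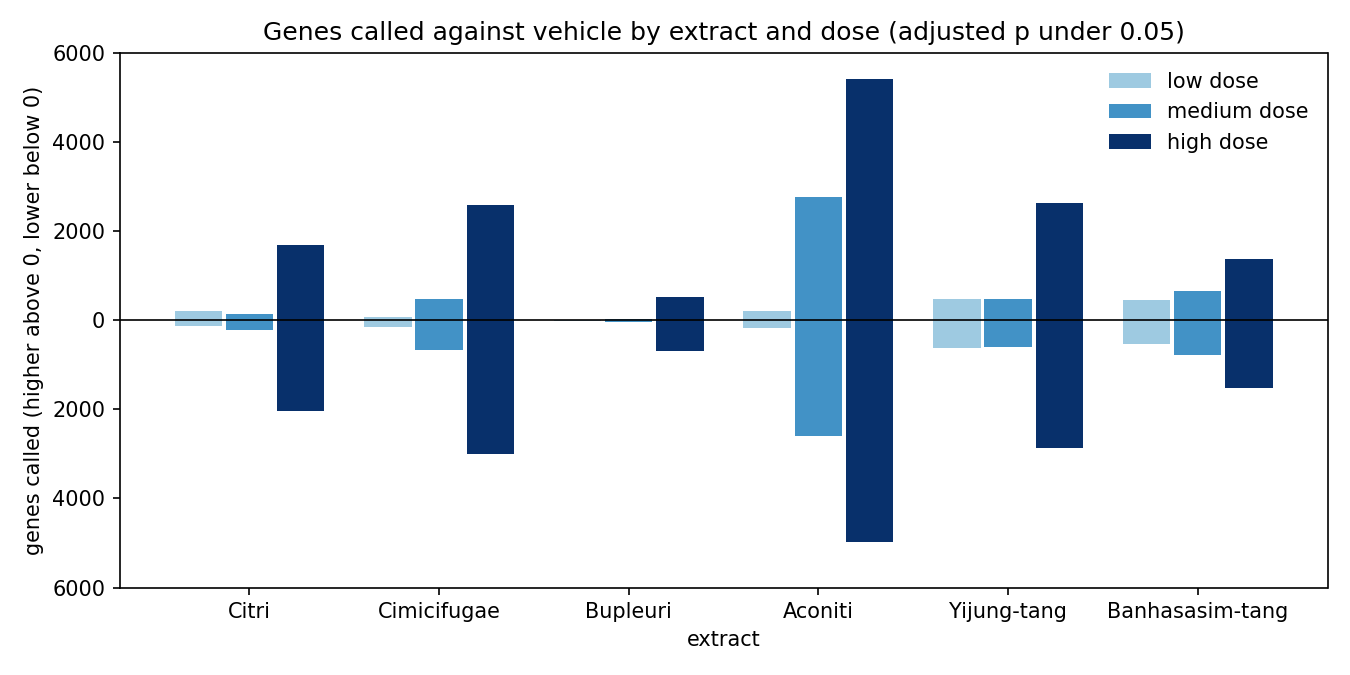
Number of genes called against the vehicle by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (vertical axis) at each dose, for the 6 extracts with 3 libraries per dose. Aconiti Lateralis Radix Preparata reached 10386 genes at the high dose, and Bupleuri Radix ranged from 13 to 1206.

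Citri Unshius Pericarpium was compared with the vehicle to ask which genes the peel extract changed. TXNIP, an arrestin-family protein that binds thioredoxin and is induced by glucose, rose by 4.37 ± 0.075 (log2, SE, n = 3 per group) at the high dose. Its level went from 8.71 ± 0.52 CPM (SD) in the vehicle to 181 ± 16.3 CPM (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.64e-41). The gene lies on chromosome 1 at 145992435 to 145996600 of GRCh38. ARRDC4, its close relative on chromosome 15 (97960698 to 97973838), rose by 1.92 ± 0.086 (SE) to 23.2 ± 1.71 CPM. Smaller rises were those of the protease inhibitors SERPINB3 (1.55 ± 0.11) and SERPINB4 (1.44 ± 0.178), the glycine cleavage enzyme AMT (1.10 ± 0.154), the growth factor EPGN (1.06 ± 0.133), ADSS1 (1.00 ± 0.137), FER1L4 (0.95 ± 0.097), the clock factor DBP (0.87 ± 0.147) and THEMIS2 (0.86 ± 0.116). AMT and FER1L4 were already at 0.64 and 0.56 at the low dose against the vehicle (edgeR's adjusted p = 0.0282 and 0.00138). From the low to the high dose, within the code set, they rose by 0.46 and 0.39. FAM13B fell by 1.22 on the log2 scale (SE 0.037), from 78.3 ± 1.34 to 33.7 ± 1.55 CPM (edgeR's adjusted p = 1.81e-30). The receptor phosphatase gene PTPRB and the cytokine gene TNFSF15 both changed by -1.27 (SE 0.098 and 0.089), and the receptor LGR6 by -1.16 ± 0.141. The amino acid transporter SLC38A4 (-1.09 ± 0.087), the neurofilament NEFL (-0.94 ± 0.119), LRRN3 (-0.86 ± 0.09), the metallothionein MT1E (-0.86 ± 0.087), the oxytocin receptor OXTR (-0.84 ± 0.064) and ANXA3 (-0.83 ± 0.083) fell as well.

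In the same comparison, camera called 17 of 33 gene lists, 12 of them also with an estimated correlation. Of 17 ER chaperones, which fold secreted proteins, 0 rose, 10 fell and 7 were not called (0 and 11 adjusted over the list alone; camera adjusted p = 2e-08). HSPA5 was at -0.38 ± 0.036. Of 7 AhR targets, the genes of aromatic compound metabolism, 5 rose, 0 fell and 2 were not called (5 and 0 adjusted over the list alone; camera adjusted p = 1.4e-06), among them CYP1A1 (1.06 ± 0.261) and CYP1B1 (0.60 ± 0.034). Of 21 NRF2 targets of the oxidative stress response, 10 rose, 0 fell and 11 were not called (13 and 0 adjusted over the list alone; camera adjusted p = 1.5e-06). FTL was at 0.46 ± 0.052. Of 22 cholesterol synthesis genes, 0 rose, 10 fell and 12 were not called (0 and 10 adjusted over the list alone; camera adjusted p = 3.4e-05), including LSS (-0.39 ± 0.041) and HMGCS1 (-0.37 ± 0.051). Against the low dose this list was not called (camera adjusted p = 0.056). Of 26 extracellular matrix genes, 1 rose, 11 fell and 14 were not called (1 and 13 adjusted over the list alone; camera adjusted p = 8.8e-07). THBS1 was at -0.42 ± 0.039. Of 23 mitosis genes, 11 rose, 0 fell and 12 were not called (12 and 0 adjusted over the list alone; camera adjusted p = 0.00013). CENPA was at 0.45 ± 0.084.

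Of 20 hypoxia and glycolysis genes, 11 rose, 1 fell and 8 were not called with Citri Unshius Pericarpium (12 and 1 adjusted over the list alone; camera adjusted p = 0.00014). NDRG1 was at 0.57 ± 0.055. Of 8 glucocorticoid targets, 5 rose, 1 fell and 2 were not called (6 and 1 adjusted over the list alone; camera adjusted p = 0.00086). DUSP1, a phosphatase of MAP kinases, rose by 0.73 ± 0.064 and CRISPLD2 changed by -0.52 ± 0.043. Of 13 FOXO targets, 6 rose, 2 fell and 5 were not called (7 and 2 adjusted over the list alone; camera adjusted p = 0.0013), and these include TXNIP. Apart from TXNIP, PDK4, a kinase that limits glucose oxidation, rose by 1.09 ± 0.219 and FBXO32, a ubiquitin ligase subunit, changed by -0.76 ± 0.051. Of 11 YAP targets, 0 rose, 7 fell and 4 were not called (0 and 7 adjusted over the list alone; camera adjusted p = 9.3e-05). CCN2 was at -0.43 ± 0.059. Metallothioneins (0 up, 2 down and 3 not called, 0 and 3 adjusted over the list alone, camera adjusted p = 0.00075) and neuron markers such as NEFL (0 up, 3 down and 2 not called, 0 and 3 adjusted over the list alone, camera adjusted p = 0.0018) were lower too. Called with the preset correlation alone were the lists of TGF-beta targets (3 up, 6 down and 4 not called, 3 and 8 adjusted over the list alone, camera adjusted p = 0.0071), ribosomal proteins (0 up, 6 down and 20 not called, 0 and 6 adjusted over the list alone, camera adjusted p = 0.002), fatty acid synthesis (0 up, 4 down and 6 not called, 1 and 4 adjusted over the list alone, camera adjusted p = 0.0095), immediate early genes (6 up, 0 down and 9 not called, 6 and 1 adjusted over the list alone, camera adjusted p = 0.023) and tubulins (0 up, 3 down and 7 not called, 0 and 3 adjusted over the list alone, camera adjusted p = 0.025). With an estimated correlation, camera's adjusted p = 0.19, 0.33, 0.066, 0.15 and 0.39, in that order.

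At the medium and low dose of Citri Unshius Pericarpium, 355 (144 up and 211 down) and 323 genes (199 and 124) were called against the vehicle, and the high dose differed from the low dose in 3135 (1408 and 1727). TXNIP rose by 4.17 ± 0.072 from the low to the high dose, and at the low dose it was at 0.20 against the vehicle (edgeR's adjusted p = 0.308). Of the 3720 calls at the high dose, 2081 were also called with the same sign against the low dose. Without vehicle 1, medium 1 or medium 2 the medium-dose count was 170, 214 or 191. Without vehicle 1, vehicle 2, low 2 or low 3 the low-dose count was 54, 141, 638 or 80, and without low 3 the high dose differed from the low dose in 2007 genes. In a fit of the compared groups alone, edgeR called 727 genes at the medium dose, 1063 between high and low dose and 0 at the low dose, where 1399 had an unadjusted p under 0.05 and DESeq2, in a fit of all groups, called 379. Without the 2 libraries that stood apart, an alternative chosen after seeing the data, the medium- and low-dose counts were 557 and 122. Mitochondrially encoded genes were lower at the high than at the low dose (median -0.23, camera adjusted p = 0.03), and adjusted p = 0.59 with an estimated correlation, and low 3 had the mitochondrial share of 7.37%.

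Cimicifugae Rhizoma was compared with the vehicle in the same way. TXNIP rose by 2.82 ± 0.078 (log2, SE, n = 3 per group) at the high dose, to 61.6 ± 2.95 CPM (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 7.89e-32). ANGPTL4, an inhibitor of lipoprotein lipase, rose by 1.12 ± 0.063 from 17.6 ± 2.04 to 38.2 ± 1.63 CPM, and the inflammatory cytokine IL1B by 1.31 ± 0.122 from 3.08 ± 0.207 to 7.65 ± 1.17 CPM. The other rises were those of SERPINB3 (1.41 ± 0.111), SERPINB4 (1.34 ± 0.179), the transcription factor HSF4 (1.32 ± 0.159), EPGN (1.26 ± 0.13), AMT (1.22 ± 0.152), ADSS1 (1.07 ± 0.135) and LUCAT1 (1.06 ± 0.103), which is annotated as an antisense RNA and is uncertain for that reason. HSF4 and AMT were already at 0.68 and 0.64 at the low dose against the vehicle (edgeR's adjusted p = 0.0283 and 0.0325). From the low to the high dose they rose by 0.63 and 0.59. ANKRD1, a nuclear cofactor and YAP target, fell by 1.73 on the log2 scale (SE 0.139), from 11.9 ± 2.23 to 3.56 ± 0.505 CPM (edgeR's adjusted p = 4.43e-14). LGR6 (-1.64 ± 0.148), the long noncoding RNA UCA1 (-1.37 ± 0.119), the homeobox factor DLX3 (-1.3 ± 0.134), SYTL3 (-1.20 ± 0.105), NEFL (-1.20 ± 0.122), OXTR (-1.18 ± 0.066), the potassium channel KCNA7 (-1.15 ± 0.121) and PTPRB (-1.09 ± 0.095) fell too.

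Among its gene lists, camera called 16 of 33 for Cimicifugae Rhizoma, 10 of them also with an estimated correlation. Of 21 NRF2 targets, 20 rose, 0 fell and 1 was not called (20 and 0 adjusted over the list alone; median 0.48; camera adjusted p = 5.7e-22). They include the ferritin chain FTL (0.89 ± 0.052), the quinone reductase NQO1 (0.87 ± 0.052) and the heme oxygenase HMOX1 (0.76 ± 0.046). Of 7 AhR targets, 6 rose, 0 fell and 1 was not called (6 and 0 adjusted over the list alone; camera adjusted p = 9.8e-11). ALDH3A1 was at 2.54 ± 0.311, CYP1A1 at 1.74 ± 0.244 and CYP1B1 at 1.01 ± 0.034. Of 13 TGF-beta targets, 0 rose, 11 fell and 2 were not called (0 and 11 adjusted over the list alone; camera adjusted p = 4e-10), among them the smooth muscle actin ACTA2 (-0.79 ± 0.064) and the transcriptional inhibitor ID3 (-0.73 ± 0.06). Of 11 YAP targets, 0 rose, 10 fell and 1 was not called (0 and 10 adjusted over the list alone; camera adjusted p = 1.2e-09). CCN2 was at -0.95 ± 0.061. Of 23 genes of the ATF4 amino acid response, 14 rose, 0 fell and 9 were not called (15 and 0 adjusted over the list alone; camera adjusted p = 5.2e-07). The cystine transporter SLC7A11 was at 0.64 ± 0.053. Of 13 FOXO targets, 8 rose, 0 fell and 5 were not called (8 and 0 adjusted over the list alone; camera adjusted p = 1.2e-05). PDK4 was at 1.20 ± 0.216.

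Of 26 extracellular matrix genes, 1 rose, 17 fell and 8 were not called with Cimicifugae Rhizoma (2 and 17 adjusted over the list alone; camera adjusted p = 4.9e-07), with elastin, ELN, at -0.95 ± 0.156. Lower too were cholesterol synthesis genes (2 up, 9 down and 11 not called, 2 and 12 adjusted over the list alone, camera adjusted p = 0.0025), metallothioneins (0 up, 2 down and 3 not called, 0 and 2 adjusted over the list alone, camera adjusted p = 0.015) and neuron markers (0 up, 3 down and 2 not called, 0 and 3 adjusted over the list alone, camera adjusted p = 0.011). Of 26 ribosomal protein genes, 0 rose, 19 fell and 7 were not called (0 and 21 adjusted over the list alone; camera adjusted p = 5.3e-06), and adjusted p = 0.13 with an estimated correlation. Of 25 nuclear oxidative phosphorylation genes, 0 rose, 12 fell and 13 were not called (0 and 14 adjusted over the list alone; camera adjusted p = 0.00059), and adjusted p = 0.4 with an estimated correlation. Of 13 mitochondrially encoded genes, 2 rose, 0 fell and 11 were not called (0 and 0 adjusted over the list alone; camera adjusted p = 0.033), and adjusted p = 0.59 with an estimated correlation. The third high-dose library had a mitochondrial share of 7.695%, against 5.435% and 5.321% in the others of its group. DNA replication (1 up, 8 down and 14 not called, 1 and 10 adjusted over the list alone, camera adjusted p = 0.031), immediate early (5 up, 1 down and 9 not called, 5 and 1 adjusted over the list alone, camera adjusted p = 0.026) and tubulin (0 up, 4 down and 6 not called, 0 and 4 adjusted over the list alone, camera adjusted p = 0.023) genes were called with the preset correlation, with camera's adjusted p = 0.28, 0.15 and 0.38 with an estimated correlation.

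At the medium and low dose of Cimicifugae Rhizoma, 1140 (467 up and 673 down) and 219 genes (64 and 155) were called, and the high dose differed from the low dose in 4317 (2004 and 2313). TXNIP rose by 2.34 ± 0.073 from the low to the high dose. Of the 5592 calls at the high dose, 3553 were also called with the same sign against the low dose. Without vehicle 1, vehicle 3, medium 2 or medium 3 the medium-dose count was 643, 716, 631 or 686. Each of the 6 libraries moved the low-dose count, to 81, 139 and 96 without vehicle 1, 2 and 3 and to 116, 125 and 96 without low 1, 2 and 3. It was 338 without the 2 libraries that stood apart, left out after seeing the data. In a fit of the compared groups alone, edgeR called 2866 genes at the high dose and 1567 between high and low dose.

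Bupleuri Radix gave smaller changes. CCN1, a matricellular protein and YAP target on chromosome 1 (85580761 to 85583962), rose by 1.00 ± 0.053 (log2, SE, n = 3 per group) from 204 ± 14.3 to 409 ± 23.2 CPM (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 8.67e-20). The neutrophil chemokine CXCL8 rose by 0.93 ± 0.115, the thrombin receptor THBD by 0.84 ± 0.104 and IL1B by 0.79 ± 0.129. Further rises were those of ADAMTS6 (0.68 ± 0.059), NPTX1 (0.67 ± 0.144), IGFBP1 (0.65 ± 0.091), the BMP antagonist GREM1 (0.64 ± 0.067), the stress cytokine GDF15 (0.58 ± 0.128) and RGMB (0.57 ± 0.058). ID3, an inhibitor of differentiation factors that responds to BMP, fell by 0.92 on the log2 scale (SE 0.06), from 234 ± 5.59 to 124 ± 7.68 CPM (edgeR's adjusted p = 1.53e-16). Its relative ID2 changed by -0.86 ± 0.073 and the BMP signal transducer SMAD9 by -0.83 ± 0.118. DLX3 (-1.51 ± 0.139), SAMD11 (-1.15 ± 0.05), LGR6 (-1 ± 0.138), the retinoic acid carrier CRABP2 (-0.91 ± 0.133), the growth factor PGF (-0.89 ± 0.138) and SELENOW (-0.83 ± 0.05) fell too.

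For Bupleuri Radix, camera called 16 of 33 lists, 14 of them also with an estimated correlation. Of 21 NRF2 targets, 12 rose, 0 fell and 9 were not called (15 and 0 adjusted over the list alone; camera adjusted p = 7.7e-19). FTH1 was at 0.57 ± 0.058 and HMOX1 at 0.51 ± 0.046. Of 23 ATF4 genes, 9 rose, 0 fell and 14 were not called (12 and 0 adjusted over the list alone; camera adjusted p = 1.2e-11). STC2 was at 0.38 ± 0.035. Of 22 NF-kB genes of inflammation, 7 rose, 3 fell and 12 were not called (9 and 3 adjusted over the list alone; camera adjusted p = 6.5e-06). Of 11 YAP targets, 5 rose, 0 fell and 6 were not called (6 and 0 adjusted over the list alone; camera adjusted p = 5e-06), with the coagulation factor receptor F3 at 0.55 ± 0.048. Of 13 TGF-beta targets, 1 rose, 6 fell and 6 were not called (1 and 6 adjusted over the list alone; camera adjusted p = 3.1e-06). Of 26 extracellular matrix genes, 1 rose, 10 fell and 15 were not called (1 and 12 adjusted over the list alone; camera adjusted p = 9.5e-07). ELN was at -0.87 ± 0.156. Of 7 AhR targets, 4 rose, 0 fell and 3 were not called (4 and 0 adjusted over the list alone; camera adjusted p = 5.3e-05). ALDH3A1 was at 1.15 ± 0.356.

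Lower with Bupleuri Radix, by medians of -0.08 each, were mitosis genes (0 up, 4 down and 19 not called, 1 and 7 adjusted over the list alone, camera adjusted p = 0.00086) and DNA replication genes (0 up, 2 down and 21 not called, 0 and 2 adjusted over the list alone, camera adjusted p = 0.00034). So were fatty acid synthesis genes (0 up, 3 down and 7 not called, 1 and 4 adjusted over the list alone, camera adjusted p = 0.0064), metallothioneins (0 up, 3 down and 2 not called, 0 and 3 adjusted over the list alone, camera adjusted p = 0.00051) and neuron markers (0 up, 2 down and 3 not called, 0 and 2 adjusted over the list alone, camera adjusted p = 0.0074). The list of immediate early genes (5 up, 0 down and 10 not called, 6 and 2 adjusted over the list alone, camera adjusted p = 0.0021) was higher, with EGR1 at 0.44 ± 0.1. Cholesterol synthesis genes were 0 up, 4 down and 18 not called (0 and 4 adjusted over the list alone, camera adjusted p = 0.0054). Heat shock genes (3 up, 1 down and 10 not called, 3 and 1 adjusted over the list alone, camera adjusted p = 0.028) and interferon genes (0 up, 2 down and 18 not called, 0 and 3 adjusted over the list alone, camera adjusted p = 0.036) were called with the preset correlation, with camera's adjusted p = 0.12 and 0.47 with an estimated correlation. At the medium and low dose, 71 (35 up and 36 down) and 13 genes (3 and 10) were called, and the high dose differed from the low dose in 752 (330 and 422). Of the 1206 calls at the high dose, 550 were also called with the same sign against the low dose. Without vehicle 1 the high-dose count was 782. The medium-dose count was 13, 23 and 44 without vehicle 1, 2 and 3 and 28, 21 and 24 without medium 1, 2 and 3. The low-dose count was 6, 5, 4 and 3 without vehicle 1, vehicle 2, low 2 and low 3, and the count between high and low dose was 496, 501 and 501 without high 1, high 2 and low 3. Medium- and low-dose counts were 126 and 31 in a fit of the compared groups alone, 199 and 116 without the filter on low counts, and at the low dose 25 with DESeq2 (9 up and 16 down). They were 127 and 37 without the 2 libraries of set 5 that stood apart, left out after seeing the data.

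At the high dose Aconiti Lateralis Radix Preparata had the most calls. GDF15, a cytokine of the cellular stress response on chromosome 19 (18374731 to 18389176), rose by 6.83 ± 0.083 (log2, SE, n = 3 per group) from 3.83 ± 0.619 to 437 ± 11.9 CPM (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 7.53e-49). At the medium and low dose it was higher by 3.73 and 0.94. The chemokines CXCL3 (5.21 ± 0.229), CXCL2 (5.20 ± 0.259) and CXCL8 (4.44 ± 0.087) rose, CXCL8 from 4.96 ± 0.419 to 108 ± 6.79 CPM. The pseudokinase TRIB3 rose by 4.32 ± 0.056 to 385 ± 2.65 CPM, and the stress transcription factor ATF3 by 4.74 ± 0.121. Further rises were those of KCP (5.08 ± 0.234), the neurotrophin receptor NGFR (4.82 ± 0.151) and the hexokinase-like HKDC1 (4.74 ± 0.133). The guanine exchange factor VAV3 fell by 3.72 on the log2 scale (SE 0.119), from 19 ± 1.52 to 1.45 ± 0.156 CPM (edgeR's adjusted p = 3.42e-31). RAB7B (-3.34 ± 0.12), the matricellular CCN4 (-3.26 ± 0.112), FAM13C (-3.17 ± 0.163), LGR6 (-3.10 ± 0.19), RASL11A (-3.04 ± 0.165), SERPINB3 (-3.03 ± 0.204), the growth factor TGFB3 (-2.95 ± 0.097) and TCAF2 (-2.91 ± 0.117) fell as well.

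The small mitochondrial ribosomal RNA MT-RNR1 rose by 4.32 ± 0.091 with Aconiti Lateralis Radix Preparata, from 680 ± 21.7 CPM in the vehicle to 13600 ± 237 CPM at the high and 15100 CPM at the medium dose. The mitochondrial share of counts was 8.995 to 9.29% in the high-dose libraries and 10.56 to 10.84% in the medium-dose libraries, against 5.025 to 5.286% in the vehicle. Of the 13 mitochondrially encoded protein genes, 0 rose, 6 fell and 7 were not called (camera adjusted p = 0.27). Of 9 genes for RNA without a poly(A) tail, a sign of RNA quality, 0 rose, 5 fell and 4 were not called (camera adjusted p = 0.1).

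With an adjusted p under 0.05, camera called 14 of 33 lists for Aconiti Lateralis Radix Preparata, 11 of them also with an estimated correlation. The ATF4 amino acid response was the list with the largest median among those that rose with Aconiti Lateralis Radix Preparata. All 23 of its genes rose (23 up, 0 down and 0 not called, 23 and 0 adjusted over the list alone, median 2.04, camera adjusted p = 3.6e-27), including the stress factor DDIT3 (3.92 ± 0.083, from 25.3 ± 1.92 to 383 ± 26 CPM). All 17 ER chaperones rose (17 up, 0 down and 0 not called, 17 and 0 adjusted over the list alone, camera adjusted p = 2e-14), with HERPUD1, a factor of ER protein degradation, at 2.7 ± 0.048 and HSPA5 at 1.86 ± 0.037 (13200 ± 413 CPM). The NF-kB list had 19 genes up, 2 down and 1 not called (19 and 2 adjusted over the list alone, camera adjusted p = 2.3e-09). The cytokine CSF2 was at 4.88 ± 0.451. For NRF2, 18 targets rose, 2 fell and 1 was not called (18 and 2 adjusted over the list alone, camera adjusted p = 1.2e-08). HMOX1 was at 3.41 ± 0.045 (613 ± 30.1 CPM) and GCLC, an enzyme of glutathione synthesis, at 1.99 ± 0.045. Lysosome and autophagy genes were 18 up, 3 down and 0 not called (18 and 3 adjusted over the list alone, camera adjusted p = 3.7e-08). The autophagy receptor SQSTM1 was at 1.98 ± 0.038. The immediate early list had 11 up, 3 down and 1 not called (11 and 3 adjusted over the list alone, camera adjusted p = 0.0011), and the FOXO list 9 up, 3 down and 1 not called (9 and 3 adjusted over the list alone, camera adjusted p = 0.0033), with IRS2, an adaptor of the insulin receptor, at 2.85 ± 0.046.

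All 23 mitosis genes fell with Aconiti Lateralis Radix Preparata (0 up, 23 down and 0 not called, 0 and 23 adjusted over the list alone, median -0.77, camera adjusted p = 1e-16). The proliferation marker MKI67 was at -1.42 ± 0.059 (274 ± 6.23 to 103 ± 8.18 CPM) and the mitotic motor KIF20A at -1.60 ± 0.046. DNA replication genes were 1 up, 21 down and 1 not called (1 and 22 adjusted over the list alone, camera adjusted p = 2.5e-12), with CCNE2, a cyclin of S phase entry, at -1.64 ± 0.087. Heat shock genes were 1 up, 12 down and 1 not called (1 and 12 adjusted over the list alone, camera adjusted p = 1.6e-06). HSPA8 was at -1.21 ± 0.039. Extracellular matrix genes were 4 up, 20 down and 2 not called (4 and 20 adjusted over the list alone, camera adjusted p = 3.1e-06). The collagen COL1A1 was at -2.05 ± 0.045 (3410 ± 96.7 to 823 ± 34.1 CPM). Tubulins were 0 up, 8 down and 2 not called (0 and 8 adjusted over the list alone, camera adjusted p = 2.2e-05), and adjusted p = 0.088 with an estimated correlation. Targets of p53 were 11 up, 4 down and 5 not called (11 and 4 adjusted over the list alone, camera adjusted p = 0.028), and adjusted p = 0.099 with an estimated correlation, with the cell cycle inhibitor CDKN1A at 1.45 ± 0.064. Astrocyte markers were 1 up, 5 down and 3 not called (1 and 5 adjusted over the list alone, camera adjusted p = 0.036), and adjusted p = 0.093 with an estimated correlation, with the glutamate transporter SLC1A3 at -2.43 ± 0.075.

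The medium and low dose of Aconiti Lateralis Radix Preparata gave 5348 (2761 up and 2587 down) and 377 calls (198 and 179), and the high dose differed from the low dose in 9934 genes (5230 and 4704). GDF15 rose by 5.89 ± 0.076 from the low to the high dose, and TRIB3 by 3.79 ± 0.053. Of the 10386 calls at the high dose, 9046 were also called with the same sign against the low dose. Without vehicle 1, vehicle 2, low 2 or low 3 the low-dose count was 190, 205, 199 or 163. It was 574 without the 2 libraries of set 5 that stood apart, left out after seeing the data.

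Yijung-tang raised TXNIP, the glucose-induced arrestin, by 4.63 ± 0.074 (log2, SE, n = 3 per group) to 216 ± 3.58 CPM at the high dose (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.03e-42). ARRDC4 rose by 1.96 ± 0.086 to 23.8 ± 0.456 CPM. HMOX1, which degrades heme and lies on chromosome 22 (35380361 to 35394214), rose by 1.87 ± 0.045 from 57.8 ± 1.03 to 212 ± 5.83 CPM. CXCL8 (1.34 ± 0.11), IL1B (1.33 ± 0.123), SERPINB3 (1.32 ± 0.113) and EPGN (1.20 ± 0.132) rose too. BCYRN1 (2.29 ± 0.157), HMGN2P5 (1.41 ± 0.211) and MT-ATP8 (1.65 ± 0.253) were called, but the first 2 have near copies in the genome and the third overlaps another gene, so their counts are uncertain. BCYRN1 and HMGN2P5 were already at 1.31 and 0.89 at the low dose against the vehicle (edgeR's adjusted p = 1.27e-06 and 0.00785). MT-ATP8 was at 577 ± 381 CPM, and without high 1, the library with the mitochondrial share of 8.209%, its rise was 0.969 (edgeR's adjusted p = 0.000605). FAM13B fell by 1.42 on the log2 scale (SE 0.037), from 78.3 ± 1.34 to 29.3 ± 0.315 CPM (edgeR's adjusted p = 3.62e-33), and MT1E, a metallothionein that binds zinc, by 1.31 (SE 0.093) from 15.6 ± 1.37 to 6.29 ± 0.505 CPM. NEFL (-1.22 ± 0.125), the microtubule protein MAP2 (-1.11 ± 0.11), TENT5B (-1.11 ± 0.149), SLC38A4 (-1.10 ± 0.088), CLIC3 (-1.09 ± 0.11), the lipid kinase DGKB (-1.07 ± 0.125), TNFSF15 (-1.03 ± 0.088) and PTPRB (-1.01 ± 0.096) fell as well.

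With Yijung-tang, camera called 12 of 33 lists, 11 of them also with an estimated correlation. NRF2 targets were 17 up, 1 down and 3 not called (17 and 1 adjusted over the list alone, camera adjusted p = 1.2e-12). NQO1 was at 0.60 ± 0.052. ER chaperones were 0 up, 13 down and 4 not called (0 and 14 adjusted over the list alone, camera adjusted p = 3.1e-10). HSPA5 was at -0.63 ± 0.036 (3650 ± 38 to 2360 ± 47.7 CPM). Extracellular matrix genes were 1 up, 21 down and 4 not called (2 and 22 adjusted over the list alone, camera adjusted p = 3.8e-09). The collagen COL3A1 was at -0.45 ± 0.061. Immediate early genes were 11 up, 1 down and 3 not called (12 and 1 adjusted over the list alone, camera adjusted p = 2.8e-07). The AP-1 subunit FOSB was at 1.85 ± 0.176 and FOS at 1.39 ± 0.186. Cholesterol synthesis genes were 1 up, 11 down and 10 not called (1 and 11 adjusted over the list alone, camera adjusted p = 6.5e-06). LSS was at -0.55 ± 0.042, and fatty acid synthesis genes were 1 up, 8 down and 1 not called (1 and 8 adjusted over the list alone, camera adjusted p = 0.0012). AhR targets were 6 up, 0 down and 1 not called (6 and 0 adjusted over the list alone, camera adjusted p = 9.9e-06). CYP1A1 was at 1.3 ± 0.256. The NF-kB list had 11 up, 2 down and 9 not called (12 and 2 adjusted over the list alone, camera adjusted p = 0.00019).

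Of 8 glucocorticoid targets, 5 rose, 1 fell and 2 were not called with Yijung-tang (5 and 1 adjusted over the list alone, camera adjusted p = 0.0034). The transcription factor KLF9 was at 0.55 ± 0.049. Metallothioneins (0 up, 4 down and 1 not called, 0 and 4 adjusted over the list alone, camera adjusted p = 0.00019) and neuron markers (1 up, 3 down and 1 not called, 1 and 3 adjusted over the list alone, camera adjusted p = 0.011) were lower. All 13 mitochondrially encoded genes rose (13 up, 0 down and 0 not called, 13 and 0 adjusted over the list alone, camera adjusted p = 3.3e-08), and adjusted p = 0.13 with an estimated correlation. The first high-dose library had a mitochondrial share of 8.209%, against 6.576% and 5.942% in the others of its group. The low-dose libraries were at 6.643%, 6.82% and 6.181%, also above the 5.025% to 5.286% of the vehicle. A difference between code sets therefore cannot be told apart from an effect of the extract here. At the medium and low dose of Yijung-tang, 1080 (470 up and 610 down) and 1096 genes (468 and 628) were called, and the high dose differed from the low dose in 3725 (1753 and 1972). Of the 5506 calls at the high dose, 2849 were also called with the same sign against the low dose. The medium-dose count was 510, 643 and 671 without vehicle 1, 2 and 3 and 588, 663 and 666 without medium 1, 2 and 3. Without vehicle 1, vehicle 2, low 1 or low 2 the low-dose count was 419, 629, 710 or 369. It was 1658 without the 2 libraries of set 5 that stood apart, left out after seeing the data.

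Banhasasim-tang raised CXCL8, the neutrophil chemokine on chromosome 4 (73740506 to 73743716), by 4.41 ± 0.086 (log2, SE, n = 3 per group), from 4.96 ± 0.419 to 106 ± 2.79 CPM at the high dose (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 8.96e-39). IL6, a cytokine of the acute phase, rose by 2.54 ± 0.123 to 22.8 ± 2.56 CPM. ICAM1, an adhesion receptor for leukocytes, rose by 2.00 ± 0.049 from 55.9 ± 2.9 to 223 ± 5.91 CPM, and the mitochondrial dismutase SOD2 by 1.80 ± 0.058 from 122 ± 2.54 to 426 ± 17.5 CPM. IER3 (2.19 ± 0.155), SERPINB2 (1.98 ± 0.055), the apoptosis inhibitor BIRC3 (1.86 ± 0.08), the cytokines IL32 (1.82 ± 0.09) and IL1B (1.82 ± 0.116) and the NF-kB regulator NFKBIZ (1.52 ± 0.109) rose too. KRT18, a keratin of intermediate filaments, fell by 1.03 on the log2 scale (SE 0.044), from 226 ± 5.28 to 111 ± 4.51 CPM (edgeR's adjusted p = 3.32e-24). LGR6 (-1.43 ± 0.142), the integrin ITGB4 (-1.22 ± 0.073), SYT12 (-1.04 ± 0.131), LONRF2 (-0.98 ± 0.059), the noncoding RNA MIAT (-0.96 ± 0.119), ANK3 (-0.90 ± 0.093), IFITM10 (-0.89 ± 0.139), DLX3 (-0.88 ± 0.125) and the amino acid transporter SLC7A8 (-0.85 ± 0.1) fell as well. SYT12 and DLX3 were already at -0.51 and -0.44 at the low dose against the vehicle (edgeR's adjusted p = 0.00748 and 0.0183).

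For Banhasasim-tang, camera called 13 of 33 lists, 8 of them also with an estimated correlation. All 22 NF-kB genes rose (22 up, 0 down and 0 not called, 22 and 0 adjusted over the list alone, median 1.75, camera adjusted p = 4.6e-69). CXCL1 was at 4.26 ± 0.324 and CSF3 at 3.79 ± 0.292. Against the low dose all 22 rose too, by a median of 1.36 (camera adjusted p = 3.6e-111). ATF4 genes were 14 up, 0 down and 9 not called (16 and 0 adjusted over the list alone, camera adjusted p = 3e-09). CEBPB was at 0.87 ± 0.127. ER chaperones were 12 up, 0 down and 5 not called (13 and 1 adjusted over the list alone, camera adjusted p = 8.7e-10). HSP90B1 was at 0.28 ± 0.029. Hypoxia and glycolysis genes were 7 up, 0 down and 13 not called (9 and 1 adjusted over the list alone, camera adjusted p = 9.4e-06), with PFKFB4, which raises glycolytic flux, at 0.53 ± 0.052. Extracellular matrix genes were 1 up, 14 down and 11 not called (2 and 19 adjusted over the list alone, camera adjusted p = 2.7e-11). COL1A2 was at -0.47 ± 0.044. Cholesterol synthesis genes were 1 up, 8 down and 13 not called (1 and 9 adjusted over the list alone, camera adjusted p = 0.0001). HMGCS1 was at -0.51 ± 0.05. Fatty acid synthesis genes (1 up, 5 down and 4 not called, 1 and 6 adjusted over the list alone, camera adjusted p = 0.003) and astrocyte markers (0 up, 4 down and 5 not called, 0 and 4 adjusted over the list alone, camera adjusted p = 0.0054) were lower, with NES, an intermediate filament of progenitors, at -0.47 ± 0.086.

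Of 20 interferon genes, 9 rose, 0 fell and 11 were not called with Banhasasim-tang (15 and 1 adjusted over the list alone, camera adjusted p = 1.3e-05), and adjusted p = 0.11 with an estimated correlation. Mitochondrially encoded genes were 10 up, 0 down and 3 not called (12 and 0 adjusted over the list alone, camera adjusted p = 5e-06), and adjusted p = 0.22 with an estimated correlation. The mitochondrial share was 6.908%, 6.022% and 6.121% in the high-dose libraries and 6.425%, 5.99% and 6.224% in the low-dose libraries. In the vehicle it was 5.025% to 5.286%, so a difference between code sets cannot be told apart from an effect of the extract here. NRF2 targets (8 up, 3 down and 10 not called, 9 and 3 adjusted over the list alone, camera adjusted p = 0.014), immediate early genes (7 up, 1 down and 7 not called, 7 and 2 adjusted over the list alone, camera adjusted p = 0.0055) and TGF-beta targets (2 up, 7 down and 4 not called, 2 and 7 adjusted over the list alone, camera adjusted p = 0.029) were called with the preset correlation, with camera's adjusted p = 0.08, 0.073 and 0.3 with an estimated correlation. At the medium and low dose of Banhasasim-tang, 1430 (653 up and 777 down) and 989 genes (450 and 539) were called, and the high dose differed from the low dose in 1146 (530 and 616). Of the 2889 calls at the high dose, 876 were also called with the same sign against the low dose. Without vehicle 1, vehicle 2 or medium 1 the medium-dose count was 824, 906 or 898, and without vehicle 1, vehicle 2, low 1 or low 2 the low-dose count was 425, 562, 492 or 593. Leaving out the 2 libraries of set 5 that stood apart, after seeing the data, gave 1570.

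**Figure D2:**
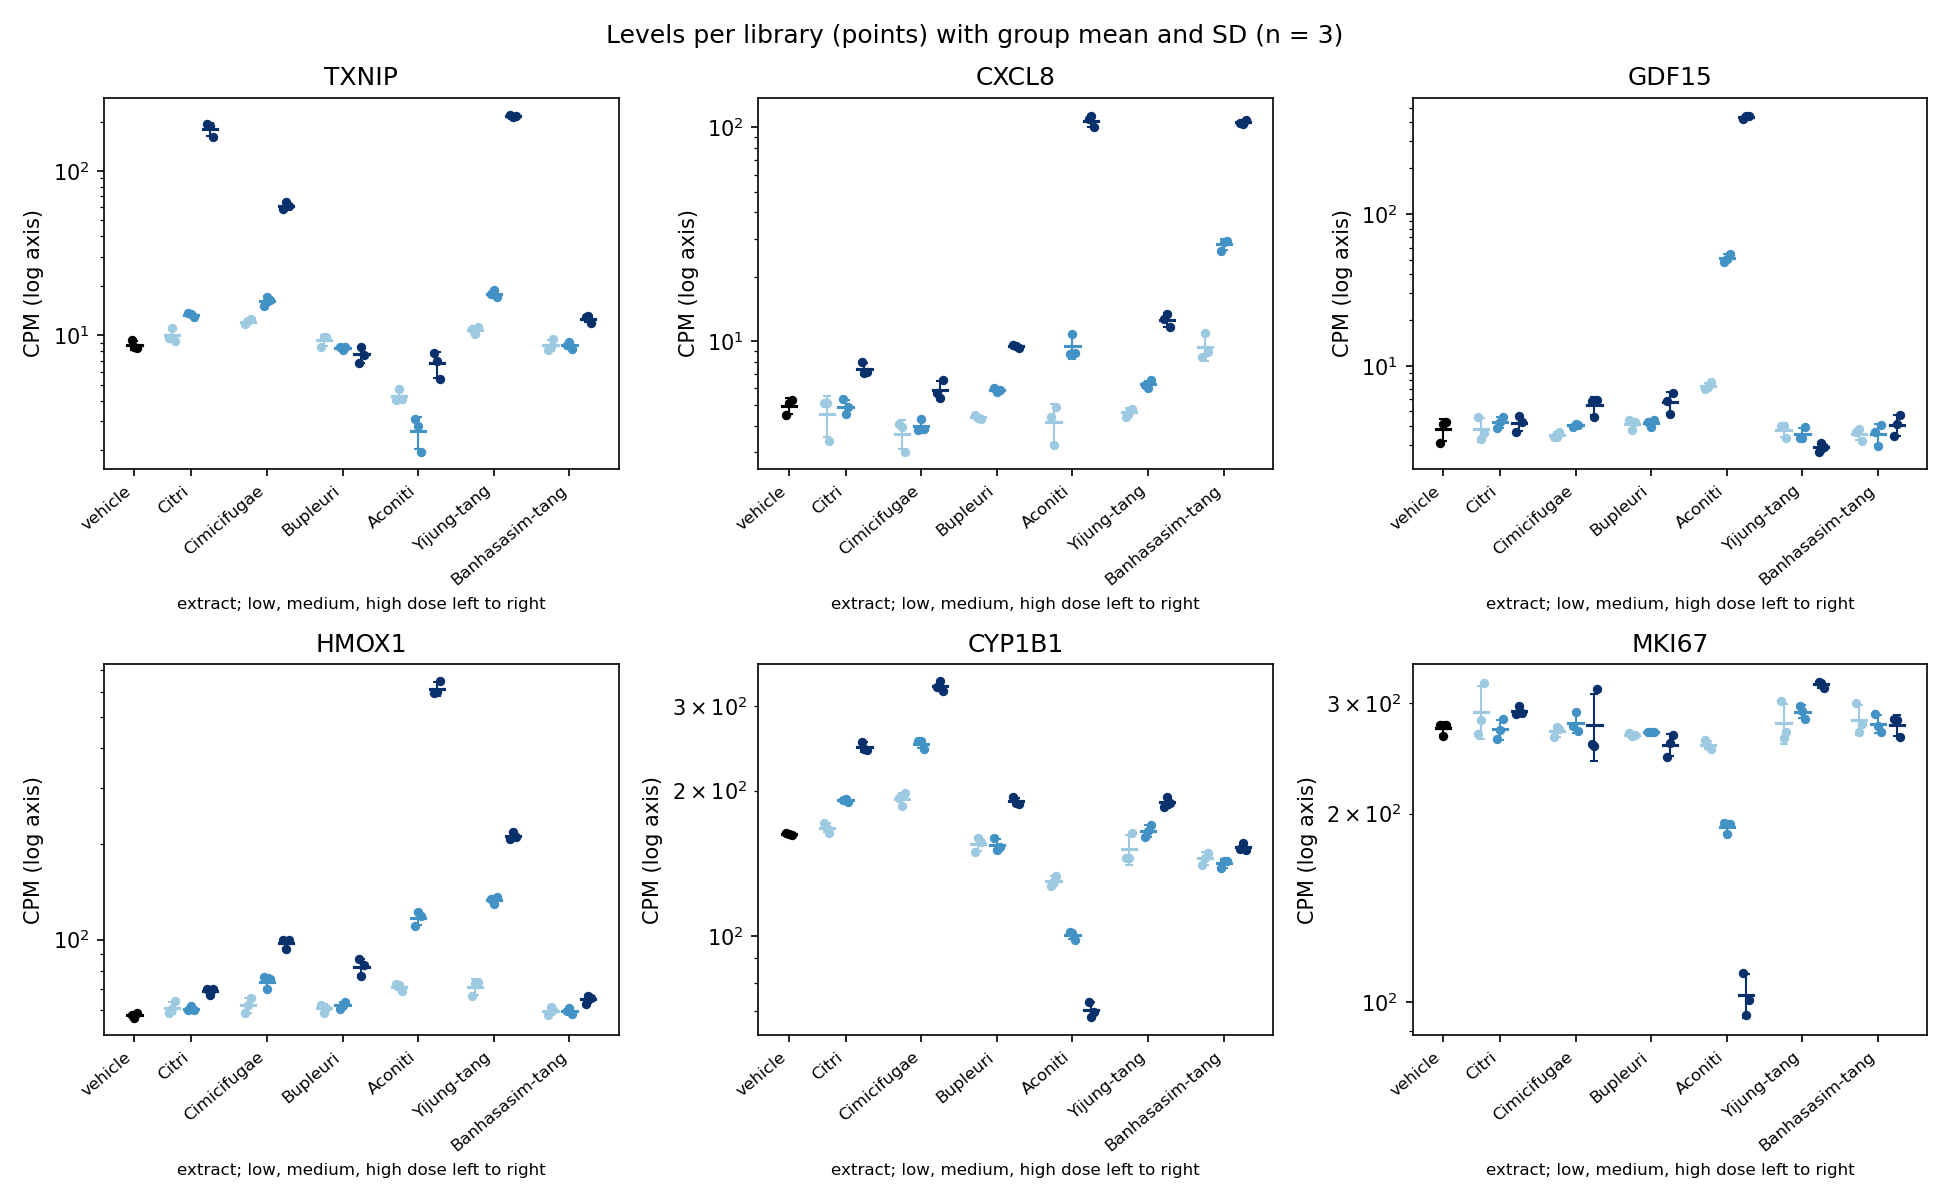
CPM of TXNIP, CXCL8, GDF15, HMOX1, CYP1B1 and MKI67 in each library (vertical axis) at each dose, by extract. GDF15 reached 437 CPM at the high dose of Aconiti Lateralis Radix Preparata, and TXNIP 216 CPM at that of Yijung-tang.

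**Figure D3:**
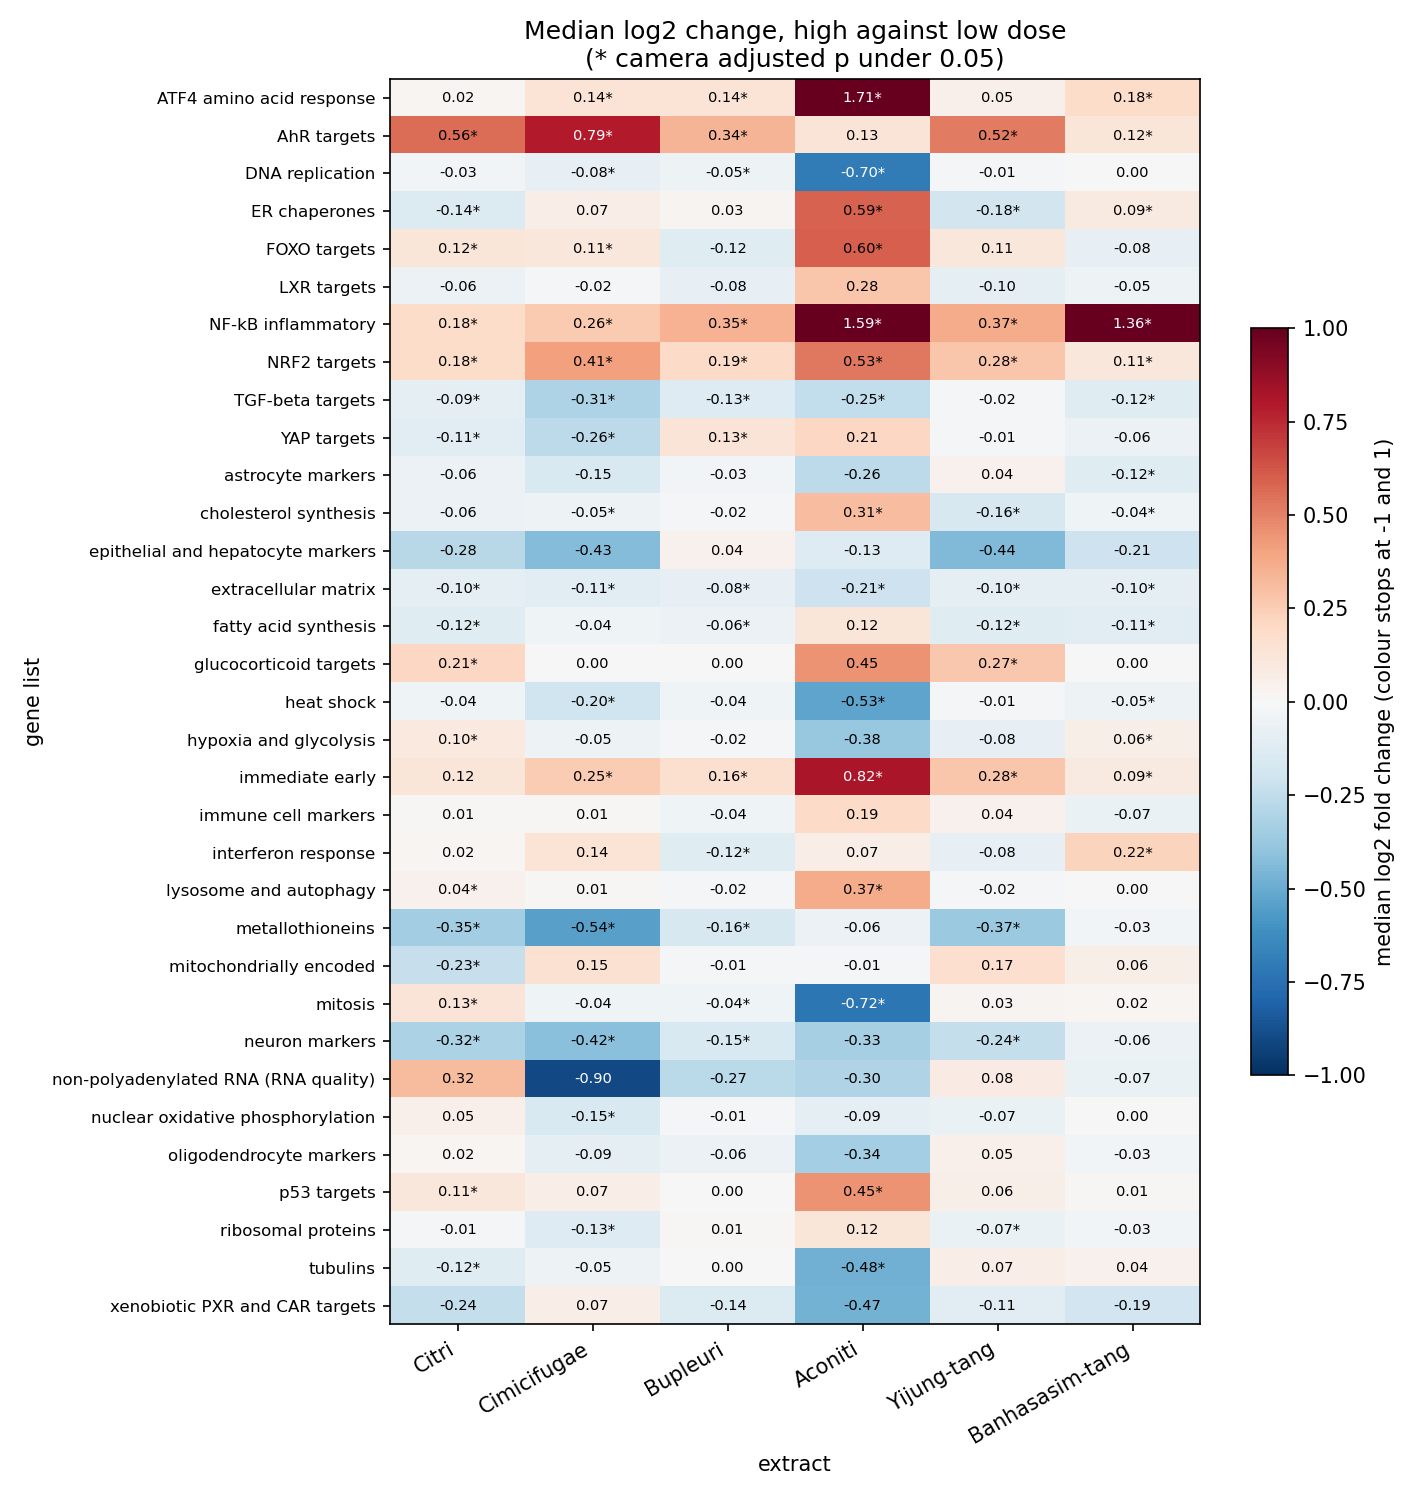
Median log2 change of each gene list (vertical axis) between the high and low dose of each extract (horizontal axis), with a star where camera's adjusted p was under 0.05. The largest medians were those of the ATF4 list with Aconiti Lateralis Radix Preparata (1.71) and of the NF-kB list with Aconiti Lateralis Radix Preparata (1.59) and Banhasasim-tang (1.36).

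Extracts of the same code set were compared directly at the high dose. Citri Unshius Pericarpium and Cimicifugae Rhizoma differed in 2110 genes (edgeR, 1119 higher and 991 lower with the first). TXNIP was higher by 1.55 with Citri Unshius Pericarpium (181 ± 16.3 against 61.6 ± 2.95 CPM, SD, n = 3 each, edgeR's adjusted p = 2e-26), ID3 by 1.24 and ANKRD1 by 1.34, while ALDH3A1 was lower by 1.55 and HSPA5 by 0.46. Without the third high-dose library of Cimicifugae Rhizoma (high 3) the count was 1125, in a fit of the compared groups alone 267 and without both libraries that stood apart, left out after seeing the data, 1345. Bupleuri Radix and Aconiti Lateralis Radix Preparata differed in 10029 genes (edgeR, 4820 higher and 5209 lower with the first). GDF15 was lower by 6.24 with Bupleuri Radix (edgeR's adjusted p = 2e-48), TRIB3 by 3.96, CXCL8 by 3.51 and HMOX1 by 2.90, while CYP1B1, an AhR target, was higher by 1.44. Yijung-tang and Banhasasim-tang differed in 4085 genes (edgeR, 1902 higher and 2183 lower with the first). With Yijung-tang TXNIP was higher by 4.09 (edgeR's adjusted p = 5.5e-42) and HMOX1 by 1.70, while CXCL8 was lower by 3.06 (12.6 ± 0.904 against 106 ± 2.79 CPM), ICAM1 by 1.89 and IL6 by 1.53.

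The difference between the 2 dose effects, high against low, was tested within each set. It was called for 1913 genes between Citri Unshius Pericarpium and Cimicifugae Rhizoma (edgeR, 953 higher and 960 lower with the first), for 7561 between Bupleuri Radix and Aconiti Lateralis Radix Preparata (3624 and 3937) and for 1730 between Yijung-tang and Banhasasim-tang (780 and 950). Genes called in both extracts with opposite signs and differing by this test numbered 115, 81 and 98. In the first of these, the count was 1162, 3009, 711 and 716 without Cimicifugae Rhizoma low 1, Cimicifugae Rhizoma high 2, Citri Unshius Pericarpium low 3 and Cimicifugae Rhizoma high 3. Without both libraries that stood apart, left out after seeing the data, it was 428. In fits of the compared groups alone the first count was 128 and the third 1111.

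Across the 15 pairs of extracts, the correlation of the high against low dose changes over 17190 genes ranged from 0.02 to 0.25. By r it was highest for Cimicifugae Rhizoma with Yijung-tang (r = 0.25), at 0.154 without Cimicifugae Rhizoma high 3, followed by Bupleuri Radix with Aconiti Lateralis Radix Preparata (r = 0.21). By r it was lowest for Banhasasim-tang with Bupleuri Radix and with Yijung-tang (r = 0.02 each), at -0.026 without Bupleuri Radix high 1 and -0.019 without Banhasasim-tang high 2. For Citri Unshius Pericarpium with Cimicifugae Rhizoma r was 0.07, from -0.021 without Cimicifugae Rhizoma high 1 to 0.169 without Citri Unshius Pericarpium low 3. For Cimicifugae Rhizoma with Banhasasim-tang it was 0.08, from 0.006 without Banhasasim-tang high 2 to 0.151 without Cimicifugae Rhizoma high 3. For the 9930 genes of at least 10 CPM it was highest for Citri Unshius Pericarpium with Yijung-tang (r = 0.58, against 0.19 over all genes), and Bupleuri Radix with Banhasasim-tang was at 0.44. By rho over all genes Yijung-tang with Citri Unshius Pericarpium and with Cimicifugae Rhizoma were level (0.39 each). Both rho and r for genes of at least 10 CPM were lowest for Citri Unshius Pericarpium with Bupleuri Radix (0.1 each), so the order of the pairs depended on the measure. No 2 extracts share a library in these comparisons, and since genes are not independent no p was computed.

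Bojungikgi-tang had 1 library per dose, so its values carry no test. CXCL8 was at 7.46, 23.4 and 81.4 CPM at the low, medium and high dose, against 4.97 ± 0.423 CPM (SD, n = 3) in the vehicle, a log2 ratio of 4.03 at the high dose. Among genes with at least 10 CPM and values ordered over the doses, the ratios of IL6 (2.55), ICAM1 (1.71), SOD2 (1.61), the cytokine IL11 (1.54), NFKBIZ (1.49), BIRC3 (1.38), the complement protein C3 (1.33), TCIM (1.32) and IL32 (1.28) were the next highest. KRT18 was at -1.11 (227 ± 5.22 to 105 CPM), PADI2, which converts arginine to citrulline, at -1.03, ITGB4 at -0.97, PLXDC1 at -0.91, ANKRD1 at -0.83, OXTR at -0.81, LRRC17 at -0.80 and OLFML2B at -0.77. PEDS1-UBE2V1 (-3.13) and BOLA2 (-1.80) are a readthrough gene and a duplicated gene, so their counts are uncertain. The median log2 ratio of the 22 NF-kB genes was 1.44, at the 100th percentile of 10000 random lists matched in expression, which describes these libraries and not the treatment, and that of 20 interferon genes 0.32. Cholesterol synthesis genes had a median of -0.14 and mitochondrially encoded genes of 0.29, also at the 100th percentile, which was -0.14 between high and low dose (percentile 0.07). The 9 genes for RNA without a poly(A) tail, a list on RNA quality, had a median of -0.61 against the vehicle (percentile 0.02 of the random lists) and of -0.01 between high and low dose (percentile 44.7). Of the 6 other extracts, the high against low dose ratios over 9930 genes were closest by r to those of Banhasasim-tang (r = 0.66, rho = 0.49), then Citri Unshius Pericarpium (r = 0.45, rho = 0.49) and Yijung-tang (r = 0.34, rho = 0.36). By rho the first 2 were level.

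Lists called in none of the 12 comparisons were the LXR targets (lowest camera adjusted p = 0.061), the PXR and CAR targets of drug metabolism (0.24), oligodendrocyte markers (0.2), immune cell markers (0.14), epithelial and hepatocyte markers (0.19) and RNA without a poly(A) tail (0.053). Among single LXR targets the cholesterol exporter ABCA1 rose by 2.52 ± 0.042 with Aconiti Lateralis Radix Preparata (edgeR's adjusted p = 6.75e-43). Of 15 astrocyte markers 9 were tested, and GFAP, AQP4, S100B, ALDH1L1, SOX2 and FABP7 were below the filter on low counts. Counts of SERPINB3 and SERPINB4, of the metallothioneins and of HSPA1A are uncertain because near copies share reads.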

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

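The test of the difference between 2 extracts' dose effects, high against low, picked out 3 results. The effects of Citri Unshius Pericarpium and Cimicifugae Rhizoma differed in 1913 genes, those of Bupleuri Radix and Aconiti Lateralis Radix Preparata in 7561 and those of Yijung-tang and Banhasasim-tang in 1730. Fits of the compared libraries alone, whose counts differ from those of the full fit, were set beside 100 splits that kept the doses and exchanged the extracts within a dose. Citri Unshius Pericarpium with Cimicifugae Rhizoma gave 128 calls, reached by 3 of 100 splits (the highest other gave 151). Bupleuri Radix with Aconiti Lateralis Radix Preparata gave 7891, reached by 8 splits (highest other 8422), and Yijung-tang with Banhasasim-tang gave 1111, reached by 8 (highest other 2347). A split that leaves 1 dose intact and mixes the other still holds the whole difference between the extracts at the intact dose, so these splits decide nothing for any of the 3. The 1913 genes were 711 without Citri Unshius Pericarpium low 3 and 716 without Cimicifugae Rhizoma high 3, and 428 without both, an alternative chosen after seeing the data.

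For the comparisons of 6 libraries the 10 splits are too few for a share under 0.05. The real count and the highest other, in fits of those libraries alone, were 267 and 0 for Citri Unshius Pericarpium against Cimicifugae Rhizoma, 10163 and 0 for Bupleuri Radix against Aconiti Lateralis Radix Preparata and 2924 and 1 for Yijung-tang against Banhasasim-tang. At the high, medium and low dose against the vehicle and for high against low they were 10363 and 0, 5762 and 0, 359 and 2, and 9793 and 0 for Aconiti Lateralis Radix Preparata. For Banhasasim-tang they were 3164 and 0, 1995 and 0, 1357 and 2, and 1055 and 1, and for Bupleuri Radix 1483 and 1, 126 and 2, 31 and 5, and 959 and 0. For Cimicifugae Rhizoma they were 2866 and 0, 1587 and 3, 230 and 5, and 1567 and 0, for Citri Unshius Pericarpium 4327 and 0, 727 and 3, 0 and 0, and 1063 and 0, and for Yijung-tang 4356 and 0, 1436 and 2, 1441 and 1, and 2522 and 0. The real count was reached by 1 split of 10, the real one, in each, except at the low dose of Citri Unshius Pericarpium, where 10 of 10 reached it.

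For the 2 patterns below, tests were written once the pattern had been seen and before their own result, except that of gene length, whose measure was replaced after its first result was seen. At the low dose against the vehicle, 1096 genes were called for Yijung-tang and 989 for Banhasasim-tang, or 1658 and 1570 without the 2 libraries named below, an alternative chosen after seeing the data. Deeper libraries are argued against: after every library was thinned to 18.9 M (mega) counts, 913 and 840 calls were left. A difference between code sets fits, since the 2 low doses, which share a set, differed from each other in 15 genes, although an effect shared by both decoctions would give the same, and the count was 28 and 92 within the other sets and between sets ran from 1 (Bupleuri Radix and Citri Unshius Pericarpium) to 913 (Aconiti Lateralis Radix Preparata and Yijung-tang). A dose effect already present at the low dose is undecided, since 64.8% of the low-dose calls of Yijung-tang and 56.9% of those of Banhasasim-tang moved the same way from the medium to the high dose.

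The third low-dose library of Citri Unshius Pericarpium and the third high-dose library of Cimicifugae Rhizoma stood apart from their groups, and their deviations were correlated with each other (r = 0.431). Gene length bias is argued against, since a smooth trend on exonic length took 3.93% and 2.86% of the variance of their deviations. This measure was chosen after a first one, the rank correlation with length (rho 0.17 and 0.15), had been seen and left the point undecided. A mixture with another dose of the same extract is argued against by correlations of -0.07 and -0.08. No biological explanation was tested.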

How the results depend on the processing

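Of 30 counts of called genes, DESeq2 moved 1 by over 1.5 times (Bupleuri Radix low dose, 25), its size factors 0 and the absence of a filter 4 (low dose of Citri Unshius Pericarpium 800 and Cimicifugae Rhizoma 340, medium and low dose of Bupleuri Radix 199 and 116). A fit of the compared groups alone, which estimates the spread from those groups only, moved 10, of which 3 rose and 7 fell. They were Citri Unshius Pericarpium medium 727, low 0 and high against low 1063, Cimicifugae Rhizoma high 2866 and high against low 1567, Bupleuri Radix medium 126 and low 31, Citri Unshius Pericarpium against Cimicifugae Rhizoma 267, and the difference of dose effects 128 in that pair and 1111 between Yijung-tang and Banhasasim-tang. Leaving out the 2 libraries that stood apart was chosen after seeing the data and moved 10: Citri Unshius Pericarpium medium 557 and low 122, Cimicifugae Rhizoma low 338, Bupleuri Radix medium 127 and low 37, Aconiti Lateralis Radix Preparata low 574, Yijung-tang low 1658, Banhasasim-tang low 1570, Citri Unshius Pericarpium against Cimicifugae Rhizoma 1345 and their difference of dose effects 428. The alternatives for the differences of dose effects were also added after seeing the data. With the compared groups alone, each count that fell involved the low dose of Citri Unshius Pericarpium, the high dose of Cimicifugae Rhizoma or that of Yijung-tang. The first 2 of these groups hold the libraries that stood apart. What caused the changes under these settings was not tested. All 120 pairs of a named gene and an extract kept call and direction. Of 177 lists called, 125 held with an estimated correlation. That estimate depends on the order of the groups in the model, so values near 0.05, such as cholesterol synthesis with Bupleuri Radix (camera adjusted p = 0.034 with an estimated correlation), can fall on either side.

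The replicate number as a block moved 1 of 30 counts (Bupleuri Radix low dose, 26), and within code sets 0 of 12. Libraries of the same set and number had a mean r of 0.0203 over 135 pairs, 3 of them over 0.1, against -0.0101 for another number in the same set (270 pairs, 2 over 0.1) and 0.00672 for the same number in other sets, and the pairing by number was not used. The highest r, 0.431, was that between Citri Unshius Pericarpium low 3 and Cimicifugae Rhizoma high 3, the 2 libraries that stood apart. They share set and number and lie at opposite doses, so what they share enters the difference of their extracts' dose effects.

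Leaving out each library in turn gave 170 to 261 calls for Citri Unshius Pericarpium medium, 54 to 638 low and 2007 to 3298 high against low, 631 to 792 for Cimicifugae Rhizoma medium and 81 to 139 low, and 782 to 893 for Bupleuri Radix high, 13 to 44 medium, 3 to 12 low and 496 to 548 high against low. It gave 163 to 320 for Aconiti Lateralis Radix Preparata low, 510 to 671 for Yijung-tang medium and 369 to 819 low, and 824 to 1056 for Banhasasim-tang medium and 425 to 709 low. Citri Unshius Pericarpium against Cimicifugae Rhizoma gave 1125 to 2718 and their difference of dose effects 711 to 3009. Each library that moved a count by over 1.5 times is named with the results.

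The correlation of dose changes ranged, over the libraries left out, from 0.132 to 0.18 for Aconiti Lateralis Radix Preparata with Banhasasim-tang, 0.086 to 0.141 with Yijung-tang, 0.154 to 0.204 with Bupleuri Radix and 0.11 to 0.162 with Cimicifugae Rhizoma, and from 0.154 to 0.268 for Cimicifugae Rhizoma with Yijung-tang. It ranged from -0.021 to 0.169 for Citri Unshius Pericarpium with Cimicifugae Rhizoma, 0.081 to 0.161 with Bupleuri Radix and 0.017 to 0.144 with Banhasasim-tang. For Banhasasim-tang it was 0.006 to 0.151 with Cimicifugae Rhizoma, -0.026 to 0.054 with Bupleuri Radix and -0.019 to 0.059 with Yijung-tang. For Bupleuri Radix it was 0.104 to 0.167 with Cimicifugae Rhizoma and 0.056 to 0.125 with Yijung-tang. For medium against low dose it was 0.05, 0.07, 0.02, 0.04 and 0.04 for Aconiti Lateralis Radix Preparata with Banhasasim-tang, Yijung-tang, Bupleuri Radix, Cimicifugae Rhizoma and Citri Unshius Pericarpium, 0.02 for Bupleuri Radix with Yijung-tang, and 0.07 for Cimicifugae Rhizoma with Bupleuri Radix and with Yijung-tang. It turned sign for Citri Unshius Pericarpium with Banhasasim-tang (-0.02), Bupleuri Radix (-0.04) and Yijung-tang (-0.02), and, within the spread between libraries, for Bupleuri Radix (-0.05) and Yijung-tang (-0.01) with Banhasasim-tang. For genes of at least 10 CPM it was 0.58, 0.32, 0.3 and 0.18 for Citri Unshius Pericarpium with Yijung-tang, Cimicifugae Rhizoma, Banhasasim-tang and Aconiti Lateralis Radix Preparata, and 0.51, 0.35, 0.28 and 0.25 for Cimicifugae Rhizoma with Yijung-tang, Bupleuri Radix, Aconiti Lateralis Radix Preparata and Banhasasim-tang. It was 0.44, 0.43 and 0.2 for Bupleuri Radix with Banhasasim-tang, Aconiti Lateralis Radix Preparata and Yijung-tang, 0.42 for Aconiti Lateralis Radix Preparata with Banhasasim-tang and 0.26 for Yijung-tang with Banhasasim-tang. Genes under the filter on low counts were out of reach at this depth.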

Other observations

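Comparisons of high with low dose share no library between extracts, and in these camera called 3 lists in the same direction for all 6, though not always each gene. Camera called NRF2 targets up, and the 21 genes were 11 up, 0 down and 10 not called with Citri Unshius Pericarpium (13 and 0 adjusted over the list alone, adjusted p = 2.1e-08), 20 up, 0 down and 1 not called with Cimicifugae Rhizoma (20 and 0 adjusted over the list alone, adjusted p = 1.7e-26) and 11 up, 0 down and 10 not called with Bupleuri Radix (16 and 0 adjusted over the list alone, adjusted p = 2.5e-23). They were 18 up, 2 down and 1 not called with Aconiti Lateralis Radix Preparata (18 and 2 adjusted over the list alone, camera adjusted p = 1.8e-09), 16 up, 0 down and 5 not called with Yijung-tang (18 and 1 adjusted over the list alone, camera adjusted p = 1.2e-14) and 6 up, 1 down and 14 not called with Banhasasim-tang (7 and 2 adjusted over the list alone, camera adjusted p = 0.00032). In this list NQO1 rose in all 6 (by 0.442, 0.791, 0.478, 0.639, 0.498 and 0.223 in that order), while HMOX1 was not called with Banhasasim-tang (0.122, edgeR's adjusted p = 0.11). Camera called extracellular matrix genes down, and the 26 genes were 0 up, 11 down and 15 not called with Citri Unshius Pericarpium (1 and 17 adjusted over the list alone, camera adjusted p = 5.1e-08), 1 up, 14 down and 11 not called with Cimicifugae Rhizoma (1 and 15 adjusted over the list alone, camera adjusted p = 0.00086) and 1 up, 6 down and 19 not called with Bupleuri Radix (1 and 12 adjusted over the list alone, camera adjusted p = 9.3e-06). They were 3 up, 18 down and 5 not called with Aconiti Lateralis Radix Preparata (3 and 18 adjusted over the list alone, camera adjusted p = 3e-06), 1 up, 14 down and 11 not called with Yijung-tang (1 and 14 adjusted over the list alone, camera adjusted p = 6e-07) and 1 up, 10 down and 15 not called with Banhasasim-tang (1 and 12 adjusted over the list alone, camera adjusted p = 4.1e-10). With an estimated correlation camera's adjusted p = 0.15 for Cimicifugae Rhizoma and 0.051 for Bupleuri Radix. Camera called NF-kB genes up, and the 22 genes were 7 up, 1 down and 14 not called with Citri Unshius Pericarpium (8 and 1 adjusted over the list alone, adjusted p = 0.017), 9 up, 1 down and 12 not called with Cimicifugae Rhizoma (9 and 1 adjusted over the list alone, adjusted p = 0.0036) and 10 up, 1 down and 11 not called with Bupleuri Radix (11 and 1 adjusted over the list alone, adjusted p = 3.1e-15). They were 19 up, 2 down and 1 not called with Aconiti Lateralis Radix Preparata (19 and 2 adjusted over the list alone, camera adjusted p = 1.8e-11), 12 up, 1 down and 9 not called with Yijung-tang (15 and 1 adjusted over the list alone, camera adjusted p = 1.9e-07) and 22 up, 0 down and 0 not called with Banhasasim-tang (22 and 0 adjusted over the list alone, camera adjusted p = 3.6e-111). With an estimated correlation camera's adjusted p = 0.092 for Citri Unshius Pericarpium. For it and Cimicifugae Rhizoma this list was not called against the vehicle. Of 17 ER chaperones, camera called the list down for 2 extracts, 0 up, 10 down and 7 not called with Citri Unshius Pericarpium (1 and 12 adjusted over the list alone, adjusted p = 1.6e-07) and 0 up, 13 down and 4 not called with Yijung-tang (0 and 13 adjusted over the list alone, adjusted p = 1.2e-12). It was called up for 2 more, 17 up, 0 down and 0 not called with Aconiti Lateralis Radix Preparata (17 and 0 adjusted over the list alone, camera adjusted p = 1.1e-13) and 6 up, 0 down and 11 not called with Banhasasim-tang (8 and 0 adjusted over the list alone, camera adjusted p = 2.7e-08). For Cimicifugae Rhizoma and Bupleuri Radix this list was not called (camera adjusted p = 0.16 and 0.3). LGR6, a receptor for R-spondins singled out after its values were seen, fell in all 6, with log2 changes of -1.12, -1.54, -0.94, -2.54, -0.72 and -1.10.

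TXNIP rose by at least 2.34 between low and high dose of Citri Unshius Pericarpium, Cimicifugae Rhizoma and Yijung-tang, within a code set, which argues against a difference between sets as the source of the rise of TXNIP and ARRDC4, in a test written after the result was seen, as was the next. A general rise of FOXO targets is undecided. The median without TXNIP was at most 0.11 in Citri Unshius Pericarpium and Yijung-tang, but members went both ways (with the first PDK4 at 1.17 and FBXO32 at -0.65). Camera included TXNIP, so it is not decisive. It called the list up between doses with Citri Unshius Pericarpium (4 up, 3 down and 6 not called, 6 and 3 adjusted over the list alone, adjusted p = 0.017) and Cimicifugae Rhizoma (6 up, 0 down and 7 not called, 6 and 0 adjusted over the list alone, adjusted p = 0.00014). Sugars supplied by the extracts are a hypothesis, since TXNIP and ARRDC4 are targets of the glucose sensor MondoA, and other such targets should rise too. Of 8 other targets tested, HBP1 (0.36) and PDK4 (1.17) rose and G6PC3 fell (-0.11) between low and high dose of Citri Unshius Pericarpium, HBP1 (0.19) and PDK4 (1.11) rose with Yijung-tang, and PDK4 (1.17) rose and KLF10 fell (-0.15) with Cimicifugae Rhizoma, so 2 of 8 rose in each of the first 2, which leaves the hypothesis undecided. Large changes of some targets were not called, so the count of 2 is a weak guide. Examples were MLXIPL at 1.26 with Citri Unshius Pericarpium (edgeR's adjusted p = 0.187) and RGS16 at -2.12 with Cimicifugae Rhizoma (edgeR's adjusted p = 0.183). PDK4 is also in the FOXO list. With Aconiti Lateralis Radix Preparata, where TXNIP rose by only 0.64 between low and high dose, 5 of the 8 rose (RGS16 by 3.63, MLXIPL by 2.55, PDK4 by 0.6, HBP1 by 0.43 and KLF10 by 0.25), so these targets also rose without a large rise of TXNIP. At both doses TXNIP was below the vehicle. Its libraries were at 4.053 to 4.741 CPM at the low and 5.427 to 7.824 CPM at the high dose, against 8.383 to 9.311 CPM in the vehicle.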
